A study of Rattus norvegicus with 8 samples.

How the data were processed

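The data are RNA-seq profiles of medial prefrontal cortex homogenate from male Sprague-Dawley rats, in 8 libraries. Per the labels, 4 libraries are from rats with high motor impulsivity (HI) and 4 from rats with low motor impulsivity (LI). Motor impulsivity was scored as premature responses in a one-choice serial reaction time task, in which a rat must withhold a nose poke until a light cue appears. The labels place HI rats in the upper quartile of that score and LI rats in the lower quartile, with 4 to 6 rats per phenotype; the 8 libraries used here are 4 HI and 4 LI. Per the labels' protocols, RNA was isolated with TRIzol, purified on RNeasy columns and made into libraries by standard Illumina protocols. The labels give no batch, date or litter. The labels do not say outright that each library is a separate animal. The p-values of the main test of single genes and of the permutation tests therefore measure the spread between these libraries.

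Each library has 1 deposited table of 17168 genes, named by gene symbol. Per the file headers, the deposited tables hold an expected count, a TPM and an FPKM value for each gene, together with transcript length. Expected counts are estimated reads per gene that need not be whole, and between 10.8% and 11.4% of the deposited expected counts in a library were not whole. The TPM values, which the authors scaled to a fixed total over all listed genes including ribosomal RNA, entered only an alternative analysis. The deposited FPKM values were not used in any test. Bowtie2 2.1.0 is named in the submitters' processing notes. The quantification program, its version, the genome build and the annotation are not given in the sources used here, so no coordinates are reported. The RefSeq transcripts named in the tables matched a current rat symbol in a RefSeq gene table (assembly GRCr8, used for names only) for 16183 of the 17168 genes. Whether counting used strand is not given in the sources used here, so reads from overlapping and antisense genes and from near-identical copies, such as ribosomal protein pseudogenes, may be split or merged.

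Expected counts were rounded to whole numbers. The rounded counts summed to between 7354416 and 9476656 per library, and between 13171 and 13478 genes had at least 1 count. Libraries were scaled by TMM factors in edgeR 4.0.16 under R 4.3.3, and low-count genes were removed with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15). HI was compared with LI by edgeR's quasi-likelihood test on 11631 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.1, the alpha stated in the series' design text. That text names Fisher's exact test; it was run as an alternative, on counts summed within each group, because a test on summed counts ignores the spread between animals. Fold changes are log2 HI minus LI, and the standard error of each is the absolute log2 fold change divided by the square root of its quasi-likelihood F. Expression levels are CPM, counts divided by the TMM-scaled library size, and log2 CPM used a prior count of 2.

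A total of 35 gene lists (receptor, channel, signalling, metabolic, stress and cell type marker genes) were fixed before the data were examined. Each was compared with all other tested genes by camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, and p was adjusted over the 35 lists with the threshold of 0.1. A camera p with the preset correlation weighs the members of a list against other genes. It does not take the correlation between members from these libraries, and so does not fully measure the spread between libraries. Camera with a correlation estimated from the data, fry, camera on ranks, and an exact two-sided permutation test of each library's mean over a list (70 assignments) were alternatives. A list score is the mean over its tested genes of each library's log2 CPM minus the gene's mean over the 8 libraries. The median of a list without a library, or with a covariate, is that of HI minus LI in log2 CPM, given beside the same median over all 8 libraries. Members of a list that passed 0.1 were also counted with p adjusted over the list alone.

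The rule for the genes named in the text was fixed at the same time. It takes first, among genes past the threshold whose HI and LI values do not overlap, the 10 with the largest rise and the 10 with the largest fall. If that gives fewer than 12 genes, the genes with the smallest p fill the number up to 12, given as values. It adds the 3 members with the smallest p for each list past its threshold, and at most 1 member for each other list. It always includes Htr2a, Htr2c, Drd1, Drd2, Maoa, Gria1, Grin2b, Grm5, Gad1, Bdnf, Fos and Nmur2. A few genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

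The tests were run on simulated counts for the HI against LI comparison, drawn for 11569 genes from the real means and library sizes with 99 genes changed 1.5-fold and 100 genes changed 2-fold. The quasi-likelihood test recovered 14.1% of the 1.5-fold changes and 64% of the 2-fold changes, with 11 false calls among 89. DESeq2 recovered 29.3% and 84%, with 48 false calls among 161, and edgeR's exact test 26.3% and 82%, with 36 among 144. Fisher's exact test on summed counts made 6264 false calls among 6457. In a simulation of the lists, camera recovered the 1 list that had been shifted and called no other, as did camera with an estimated correlation (adjusted p = 0.0107), fry (adjusted p = 0.00749) and camera on ranks, while the exact permutation test did not recover it (adjusted p = 0.25). Genes were drawn independently in both simulations. The simulations therefore do not show how many genes a test would wrongly call where genes vary together across libraries. Nor do they show how many lists camera would wrongly call where the members of a list vary together.

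Alternatives fixed in advance were other scaling factors (RLE, upper quartile), no low-count filter and a filter of 1 CPM in at least 4 libraries (11816 genes kept), DESeq2 1.42.0, limma-voom with and without library weights, edgeR's exact test, robust dispersion, log2(TPM + 0.1) and log2(TPM + 1), other thresholds, a replicate block, and leaving out each library in turn. Alternatives added after seeing the data were the ribosomal RNA share as a covariate, a term separating replicates 1 and 2 from replicates 3 and 4, leaving out HI4 with LI3 or HI1 with LI2, leaving out ribosomal RNA genes, and log2 CPM corrected for each library's trend over transcript length (loess span 0.3). GC content was not tested, because no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.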

Results

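RNA was sequenced from medial prefrontal cortex, a region involved in action restraint, of rats at the high (HI) and low (LI) ends of motor impulsivity, with 4 libraries in each group. The single comparison the design implies asks which transcripts differ between inherently impulsive and non-impulsive rats. No pair of libraries within a group was identical or within sampling noise of another, so none were merged. Total counts ranged from 7354416 to 9476656 per library and did not separate the groups (two-sided exact permutation p = 0.943, n = 4 each).

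The libraries differed in their content of ribosomal RNA, the Rn45s and Rn28s transcripts. It took 25.5% of the counts in HI2, 6.12% in HI1, 3.96% in HI3 and 0.406% in HI4. In the LI group it took 6.42% in LI2, 5.44% in LI1, 1.37% in LI4 and 0.418% in LI3. The HI mean lay 5.58 percentage points above the LI mean, with an SD of 11.2 points in HI and 2.96 in LI (n = 4 each, exact permutation p = 0.571). The first principal component of log2 CPM held 51.7% of the variance. HI4 at 51.0 and LI3 at 34.6, the libraries with the least ribosomal RNA, stood apart from the other 6, which lay between -25.9 and 2.05, and the component did not separate HI from LI (exact permutation p = 0.914). Libraries with replicate numbers 1 and 2 carried 10.9% ribosomal RNA on average and those with numbers 3 and 4 carried 1.54%. Longer transcripts were relatively more abundant in HI4, by 0.13 log2 units per doubling of transcript length, and less abundant in LI1, by -0.08. This slope averaged 0.03 ± 0.07 in HI and -0.03 ± 0.04 in LI (SD, n = 4 each, exact permutation p = 0.0857).

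**Figure D1:**
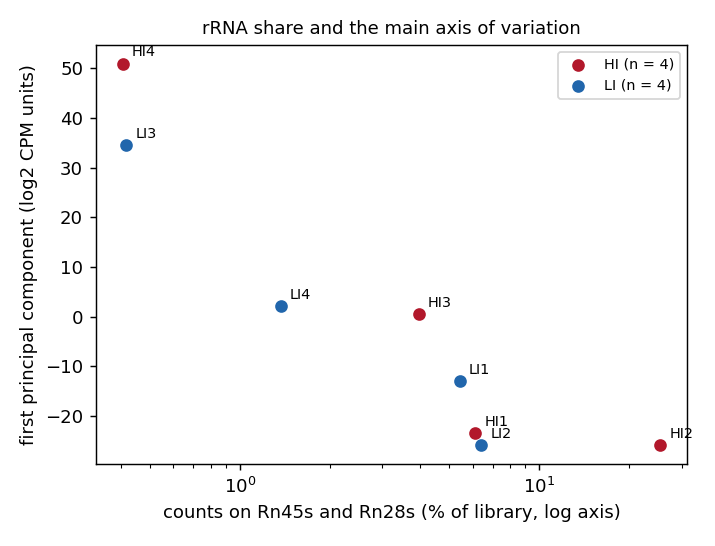
First principal component of log2 CPM (vertical axis) against the percent of counts on Rn45s and Rn28s (horizontal log axis) for each of the 8 libraries, coloured by group. HI4 and LI3 have 0.406% and 0.418% ribosomal RNA and sit highest, at 51.0 and 34.6, while HI2 has 25.5% and sits at -25.8.

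At the level of single genes, the 12 genes with the smallest p all had higher values in HI, and included ion channel, receptor and calcium transport genes. Cacna1e, which encodes the pore of the R-type voltage-gated calcium channel, stood at 239 ± 33.6 CPM in HI and 138 ± 21.3 CPM in LI (SD, n = 4 each), a log2 fold change of 0.80 ± 0.15 (SE). Grin2a, an NMDA receptor subunit, stood at 117 ± 14.3 against 71.8 ± 10.7 CPM, a log2 fold change of 0.71 ± 0.14. Grm5, a metabotropic glutamate receptor, stood at 127 ± 9.17 against 89.3 ± 7.49 CPM, a log2 fold change of 0.51 ± 0.11. In each of these genes all 4 HI libraries lay above all 4 LI libraries, but none passed the adjusted threshold in edgeR's quasi-likelihood test.

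The other 9 of the 12 genes with the smallest p had the same separation of the libraries. They included Gabrb1, a GABA-A receptor subunit (log2 fold change 0.63 ± 0.14), Kcnma1, the calcium-activated potassium channel of large conductance (0.44 ± 0.10), Slc8a1, a sodium-calcium exchanger (0.56 ± 0.13), and Atp2b4, a plasma membrane calcium pump (0.64 ± 0.15). The receptor tyrosine phosphatase gene Ptprt differed by 0.57 ± 0.11, the GTPase-activating protein gene Srgap3 by 0.47 ± 0.10 and the protocadherin gene Pcdh19 by 0.62 ± 0.13. Arl5b, an ARF-like GTPase, differed by 0.79 ± 0.16 and Xkr4 by 0.65 ± 0.14. Cacna1e was higher in HI by 0.75 log2 units within replicates 1 and 2 and by 0.85 within replicates 3 and 4, and Grin2a by 0.45 and 0.97. As HI and LI did not overlap in either gene, a higher value within both sets had to follow and is no separate support.

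**Figure D2:**
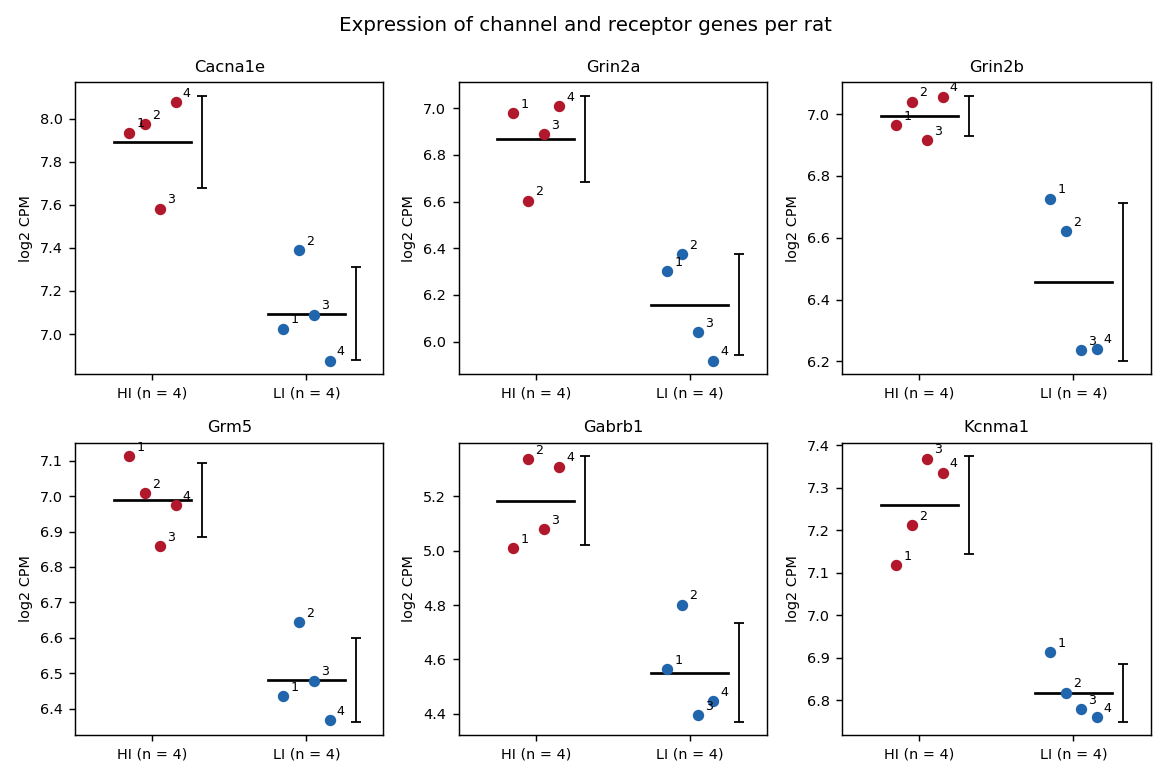
Log2 CPM of 6 channel and receptor genes in each library (points, numbered by replicate), with the group mean (line) and SD (bar) for HI and LI, n = 4 each. In all 6 genes the HI points lie above the LI points, with log2 fold changes from 0.44 (Kcnma1) to 0.80 (Cacna1e).

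Of 11631 genes tested, 0 passed an adjusted p of 0.1 in edgeR's quasi-likelihood test, in either direction, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 484 genes, 357 higher and 127 lower in HI, against 582 expected by chance. The HI and LI values did not overlap in 402 genes, 269 with HI above and 133 with HI below, where chance gives 2.86% of genes, or 332. The median absolute log2 fold change was 0.12 and the median SE 0.19. DESeq2 called 30 genes, 29 higher in HI and 1 lower, and 11 of the 12 genes above were among them (Cacna1e, adjusted p = 0.00263, and Grin2a, adjusted p = 0.00643, by DESeq2). The 1 gene that DESeq2 called lower was Fth1, ferritin heavy chain, at -0.36 ± 0.10, named here after its values were seen. edgeR's exact test called 1 gene, Cacna1e (adjusted p = 0.0336), while limma-voom, with and without library weights, and limma on log2 TPM called 0. On simulated data DESeq2 made 48 false calls among 161 and edgeR's exact test 36 among 144, against 11 among 89 for the quasi-likelihood test. The simulated genes varied independently, so these shares need not hold in the real libraries. Fisher's exact test on summed counts called 6596 genes, 1479 higher and 5117 lower in HI, but made 6264 false calls among 6457 on simulated data. It used no TMM scaling, and its median log2 fold change over genes was -0.11. With the ribosomal RNA share as a covariate, an analysis chosen after seeing the data, edgeR called 440 genes, 322 higher and 118 lower in HI, and this count was 0 without HI4 and 0 without LI3.

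Gene groups passed the threshold where single genes did not. Of the 35 lists fixed before the data were examined, 22 passed an adjusted p of 0.1 in limma's camera test, 15 higher and 7 lower in HI. The higher lists numbered 9 without HI4 and 10 without HI3. The same test also called lists in every other division of the 8 libraries into 4 against 4, from 1 to 17. Ion channel and glutamate receptor lists were higher in HI, and ribosomal protein, oxidative phosphorylation and myelin lists were lower. With a correlation estimated from the data 0 of the 22 passed, the smallest camera adjusted p being 0.138, and 6 lists had an unadjusted p under 0.05. The fry test called 3 lists, and the exact permutation test of list scores, in which 11 lists would have to reach the smallest possible p for any to pass, called 0.

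Ion channel and ionotropic glutamate receptor lists separated the HI from the LI libraries. Of 27 potassium channel genes 24 had higher values in HI, with a median log2 fold change of 0.19 (camera adjusted p = 3.68e-05, and adjusted p = 0.138 with an estimated correlation, limma). Of 28 sodium and calcium channel genes 18 were higher, with a median of 0.10, and of 18 ionotropic glutamate receptor genes 12 were higher, with a median of 0.15 (both camera adjusted p = 0.00360, and adjusted p = 0.138 with an estimated correlation, limma). These were the 3 lists called by fry, each at an adjusted p of 0.0333, and in each of them the scores of all 4 HI libraries lay above those of all 4 LI libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). Members past the threshold with p adjusted over the list alone were Kcnma1, Kcnq3 and Kcna2 among potassium channels, Cacna1e, Cacna2d1 and Scn8a among sodium and calcium channels, and Grin2a and Grin2b among ionotropic receptors; 0 passed over all genes. Kcnq3, of the M-current channel, differed by 0.40 ± 0.11, and Kcna2 by 0.58 ± 0.18. Cacna2d1, an auxiliary calcium channel subunit, differed by 0.48 ± 0.11 and Scn8a, a sodium channel of the axon initial segment, by 0.49 ± 0.14. Grin2b stood at 127 ± 5.82 CPM in HI and 88.6 ± 15.7 CPM in LI (SD, n = 4 each), a log2 fold change of 0.52 ± 0.13. In log2 CPM the median of potassium channels was 0.18, and 0.10 without LI2, that of ionotropic receptors 0.13, and 0.21 without LI3, and that of sodium and calcium channels 0.10, and 0.16 without HI2 and 0.06 without LI2. The mean length slope of the libraries was higher in HI, as these lists were. Within LI, however, LI3 had the highest slope (0.01) and the lowest potassium channel score (-0.160). LI1 had the lowest slope (-0.08) and the highest potassium channel score in LI (-0.0532). With log2 CPM corrected for transcript length the camera adjusted p was 0.000996 for potassium channels, 0.0421 for ionotropic receptors and 0.218 for sodium and calcium channels, the last no longer past the threshold, with a log2 CPM median of -0.000424.

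Other transmitter receptor lists were also higher in HI. Of 14 GABA receptor genes 11 were higher, with a median log2 fold change of 0.16 (camera adjusted p = 0.00614, and adjusted p = 0.392 with an estimated correlation, limma). Gabrb1 and Gabrb2 (0.44 ± 0.14) passed over the list alone. Without HI4 the GABA receptor call was lost (adjusted p = 0.323, limma camera) and the log2 CPM median went from 0.15 to 0.02, while it was 0.27 without HI2 and 0.26 without LI3. Of 8 metabotropic glutamate receptors 6 were higher (median 0.16, camera adjusted p = 0.0391, and adjusted p = 0.225 with an estimated correlation, limma). Grm5 passed over that list alone, while Grm7 differed by 0.20 ± 0.13 (0.12 without LI4) and Grm4 by -0.39 ± 0.20. Of 10 acetylcholine receptors 9 were higher (median 0.15, camera adjusted p = 0.0391, and adjusted p = 0.306 with an estimated correlation, limma), with Chrna4 at 0.25 ± 0.16 (0.38 without HI1 and 0.14 without HI4), Chrna5 at 0.64 ± 0.48 (0.40 without HI4 and 0.38 without LI1) and Chrm2 at 0.35 ± 0.28 (0.15 without LI1 and 0.56 without LI4). The metabotropic call was lost without HI3, HI4 or LI2 (adjusted p from 0.141 to 0.257) and with the length correction (0.201), and the acetylcholine call without HI2, HI3 or HI4 (from 0.110 to 0.257), by limma camera. For metabotropic receptors the log2 CPM median was 0.17, and 0.14, 0.12 and 0.13 without HI3, HI4 and LI2 and 0.09 with the length correction. For acetylcholine receptors it was 0.15, and 0.19, 0.12 and 0.15 without HI2, HI3 and HI4 and 0.10 without LI3.

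Serotonin and dopamine genes went in both directions. The serotonin receptor list passed (camera adjusted p = 0.0885, and adjusted p = 0.392 with an estimated correlation, limma) with 4 members higher and 4 lower and a median log2 fold change of 0.05. It held in only 1 of the 8 fits that left out a library, the one without LI2, and was lost with no low-count filter (adjusted p = 0.661), with a filter of 1 CPM in at least 4 libraries (0.326) and on ranks (0.296), by limma camera. Its log2 CPM median of 0.07 was 0.16 without HI1, -0.01 without HI2, 0.05 without HI3 and -0.03 without LI3. That median was -0.09 without a low-count filter. Htr1b, an inhibitory serotonin receptor, stood at 13.1 ± 1.97 CPM in HI and 8.11 ± 1.63 in LI (SD, n = 4 each), a log2 fold change of 0.70 ± 0.19, with all HI above all LI, and passed over the list alone. Htr2a differed by 0.49 ± 0.22, Htr1a by 0.26 ± 0.24 (0.10 without LI1, 0.48 without LI3 and 0.14 without LI4) and Htr2c by -0.14 ± 0.37, and HI and LI libraries overlapped in each. Drd1 differed by -0.06 ± 0.39 and Drd2 by -0.91 ± 0.52, the latter being -0.18 without LI2. The sign of Htr2c turned without HI1 (0.10) or LI2 (0.09), and it was -0.43 without HI2, -0.29 without LI1, -0.02 without LI3 and -0.32 without LI4. The sign of Drd1 turned without HI1 (0.13), HI3 (0.02) or LI2 (0.38), and it was -0.26 without HI2, -0.18 without HI4, -0.28 without LI1 and -0.19 without LI4. Maoa, which breaks down serotonin and noradrenaline, differed by 0.23 ± 0.11. The dopamine and noradrenaline receptor list did not pass (camera adjusted p = 0.802, limma), with a median of 0.06 but a mean of -0.06 and a test direction lower in HI, nor did the monoamine enzyme and transporter list (adjusted p = 0.549). Nmur2, the neuromedin U receptor, was removed by the low-count filter, with counts of 20, 3, 1 and 0 in HI1 to HI4 and 0, 29, 59 and 7 in LI1 to LI4.

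Activity-regulated and synaptic genes were higher in HI. All 20 immediate early genes had higher values in HI, with a median log2 fold change of 0.41 (camera adjusted p = 6.46e-09, and adjusted p = 0.225 with an estimated correlation, limma). Egr2 differed by 1.09 ± 0.40 (1.64 without LI4), Nr4a1 by 0.66 ± 0.28, Nr4a3 by 0.56 ± 0.23, Fos by 0.59 ± 0.27 (0.94 without LI4) and Bdnf by 0.23 ± 0.17 (0.14 without HI3 and 0.13 without LI2), and 0 of the 20 passed over the list alone. The list score was 0.24 ± 0.19 in HI and -0.24 ± 0.40 in LI (SD, n = 4 each, exact permutation p = 0.0857), with LI4 at 0.33 inside the HI range. Neurotrophin and growth factor receptor genes were higher in 12 of 16 (median 0.23, camera adjusted p = 0.00160, and adjusted p = 0.143 with an estimated correlation, limma). Erbb4, a neuregulin receptor, differed by 0.74 ± 0.19 and passed over the list alone, with Ntrk3 at 0.39 ± 0.13 and Egfr at 0.45 ± 0.20, and the log2 CPM median of 0.18 was 0.11 without HI4, 0.12 without LI1 and 0.28 without LI3. Of 28 synaptic vesicle genes 21 were higher (median 0.10, camera adjusted p = 0.0113, and adjusted p = 0.392 with an estimated correlation, limma). The active zone gene Bsn differed by 0.39 ± 0.10 and passed over the list alone, Syn3 differed by 0.40 ± 0.13 and Pclo by 0.71 ± 0.26 (0.38 without HI4). Of 24 postsynaptic genes 18 were higher (median 0.13, camera adjusted p = 0.0249, and adjusted p = 0.457 with an estimated correlation, limma), with Dlgap2 at 0.41 ± 0.12, Dlg2 at 0.43 ± 0.17 (0.23 without HI4) and Homer3 at -0.52 ± 0.19. Without HI4 neither synaptic list passed (adjusted p = 0.205 for vesicle and 0.323 for postsynaptic genes), and without HI3 neither did (0.229 and 0.286), while the postsynaptic list was also lost without LI2 (0.410) and with the length correction (0.215), by limma camera. In log2 CPM the median of vesicle genes was 0.08, and 0.15, 0.18, 0.03 and 0.07 without HI1, HI2, HI3 and HI4 and 0.16 without LI3, and that of postsynaptic genes was 0.14, and 0.09 without HI3, 0.04 without HI4, 0.07 without LI2 and 0.07 with the length correction.

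Regulators of G protein signalling were higher in 16 of 27, with a median of 0.04 (camera adjusted p = 0.00614, and adjusted p = 0.310 with an estimated correlation, limma). Rgs16 (0.84 ± 0.23), the receptor kinase gene Adrbk2 (0.43 ± 0.11) and the cyclic AMP phosphodiesterase gene Pde4d (0.47 ± 0.12) passed over the list alone, and all HI libraries lay above all LI libraries in each. The log2 CPM median of 0.05 was 0.02 without HI1, 0.14 without HI2, 0.03 without HI3, 0.02 without HI4, 0.11 without LI2 and 0.09 without LI3.

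Ribosomal protein and mitochondrial respiratory chain genes were lower in HI by small amounts. All 38 cytosolic ribosomal protein genes had lower values in HI, with a median log2 fold change of -0.22 (camera adjusted p = 1.41e-10, and adjusted p = 0.225 with an estimated correlation, limma). Rpl32 differed by -0.28 ± 0.10 and Rpl19 by -0.23 ± 0.10, with all HI below all LI in both. The list score was -0.12 ± 0.21 in HI and 0.12 ± 0.13 in LI (SD, n = 4 each, exact permutation p = 0.114), with HI4 lowest at -0.41. Of 35 oxidative phosphorylation subunit genes 33 were lower, with a median of -0.13 (camera adjusted p = 1.48e-04, and adjusted p = 0.225 with an estimated correlation, limma), and the score of every HI library lay below that of every LI library (two-sided exact permutation p = 0.0286). Ndufa4 differed by -0.21 ± 0.09, Ndufb9 by -0.25 ± 0.13 and Cox7a2 by -0.20 ± 0.11. Without HI4 the log2 CPM median went from -0.23 to -0.13 for ribosomal proteins and from -0.14 to -0.07 for oxidative phosphorylation. These transcripts are short, and log2 fold change was larger for longer transcripts over all tested genes (Spearman correlation = 0.291 across genes, which are not independent replicates). With the length correction the camera adjusted p was 0.000996 for ribosomal proteins and 0.257 for oxidative phosphorylation, the latter no longer past the threshold, with a log2 CPM median of -0.03.

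Markers of cell types other than cortical neurons also differed between the groups. Oligodendrocyte and myelin markers were lower in HI in 22 of 22 genes (median -0.55, camera adjusted p = 1.57e-06, and adjusted p = 0.392 with an estimated correlation, limma), with Mbp at -0.91 ± 0.34, Mal at -0.69 ± 0.32 and Gpr37 at -0.50 ± 0.23, and at -0.44, -0.28 and -0.20 without LI2. Markers of striatal projection neurons were lower in 14 of 15 (median -0.54, camera adjusted p = 0.00655, and adjusted p = 0.457 with an estimated correlation, limma), with Adora2a at -1.96 ± 0.74, Penk at -0.62 ± 0.30 and Gpr6 at -1.31 ± 0.69, and at -0.50, -0.31 and 0.00 without LI2. LI2 had the highest score in both lists, 1.12 for myelin and 1.18 for striatal markers. Myelin markers had a log2 CPM median of -0.43, and -0.13 without LI2 and -0.73 without LI1, and that of striatal markers was -0.42, and -0.02 without LI2 and -0.32 without HI1. Without LI2 the adjusted p was 0.0687 for myelin and 0.662 for striatal markers, the striatal call was also lost without HI1 (0.105), and the myelin call was lost when HI1 and LI2 were left out together (0.157), by limma camera. Markers of meninges and fibroblasts were higher in 14 of 15 (median 1.58, camera adjusted p = 6.19e-07, and adjusted p = 0.327 with an estimated correlation, limma). Slc6a13 differed by 1.80 ± 0.57, Aldh1a2 by 1.70 ± 0.70 and Ogn by 1.68 ± 0.69, and without HI1 these values were 1.09, 0.74 and 0.67, while the log2 CPM median of the list went from 1.41 to 0.72. The meningeal score was 2.14 in HI1 and -0.65 in HI4, and -1.45 in LI1, -1.29 in LI3 and 0.35 in LI4.

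Endothelial and pericyte markers were higher in 16 of 19 (median 0.24, camera adjusted p = 0.00705, and adjusted p = 0.392 with an estimated correlation, limma), with Vtn at 0.81 ± 0.39 (0.27 without HI1), Abcc9 at 0.39 ± 0.22 (0.19 without HI4) and Kdr at 0.45 ± 0.29 (0.12 without HI1). The call was lost without HI1 (adjusted p = 0.277, limma camera), where the log2 CPM median went from 0.25 to 0.08, and the median was 0.13 without LI3. Microglia and macrophage markers were lower in 16 of 18 (median -0.22, camera adjusted p = 1.31e-04, and adjusted p = 0.143 with an estimated correlation, limma). Tmem119, a marker of resident microglia, differed by -0.75 ± 0.21 with all HI below all LI and passed over the list alone, and the log2 CPM median of -0.21 was -0.12 without HI4. Aif1 differed by -0.32 ± 0.14, while Mrc1, found in border macrophages, differed by 1.79 ± 0.63 (0.89 without HI1). Markers of pyramidal neurons were higher in 15 of 21 (median 0.14, camera adjusted p = 0.00810, and adjusted p = 0.306 with an estimated correlation, limma), with Rorb at 0.58 ± 0.22 (0.34 without HI4), Rasgrf2 at 0.45 ± 0.18 and Tbr1 at 0.30 ± 0.13. The call was lost without HI4 (adjusted p = 0.181, limma camera), although the log2 CPM median was 0.16 with and without HI4, and 0.28 without HI1. Interneuron markers were lower in 16 of 24 (median -0.16, camera adjusted p = 0.0559, and adjusted p = 0.392 with an estimated correlation, limma). Gad1, which makes GABA, differed by -0.42 ± 0.18 and Dlx1 by -0.47 ± 0.21 (-0.23 and -0.21 without LI4), and Reln by 0.36 ± 0.12, and the call was lost without HI1 (adjusted p = 0.126), HI2 (0.214) or LI4 (0.498), by limma camera. The log2 CPM median of -0.12 was -0.14, -0.09 and -0.05 in those fits, -0.20 without LI1 and -0.18 without LI2. Oligodendrocyte precursor markers were lower in 8 of 13 (median -0.14, camera adjusted p = 0.0885, and adjusted p = 0.392 with an estimated correlation, limma), with C1ql1 at -0.31 ± 0.13, Tmem100 at -0.29 ± 0.15 and Bcas1 at -0.64 ± 0.33 (-0.42 without LI2), and the call was lost without HI2, HI3, LI2, LI3 or LI4 (adjusted p from 0.157 to 0.410), with RLE factors (0.103), with no low-count filter (0.135) and on ranks (0.168), by limma camera. The log2 CPM median of -0.13 lay between -0.22 and -0.11 in those fits that left out a library, and was -0.21 without HI4 and -0.28 without LI1.

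**Figure D3:**
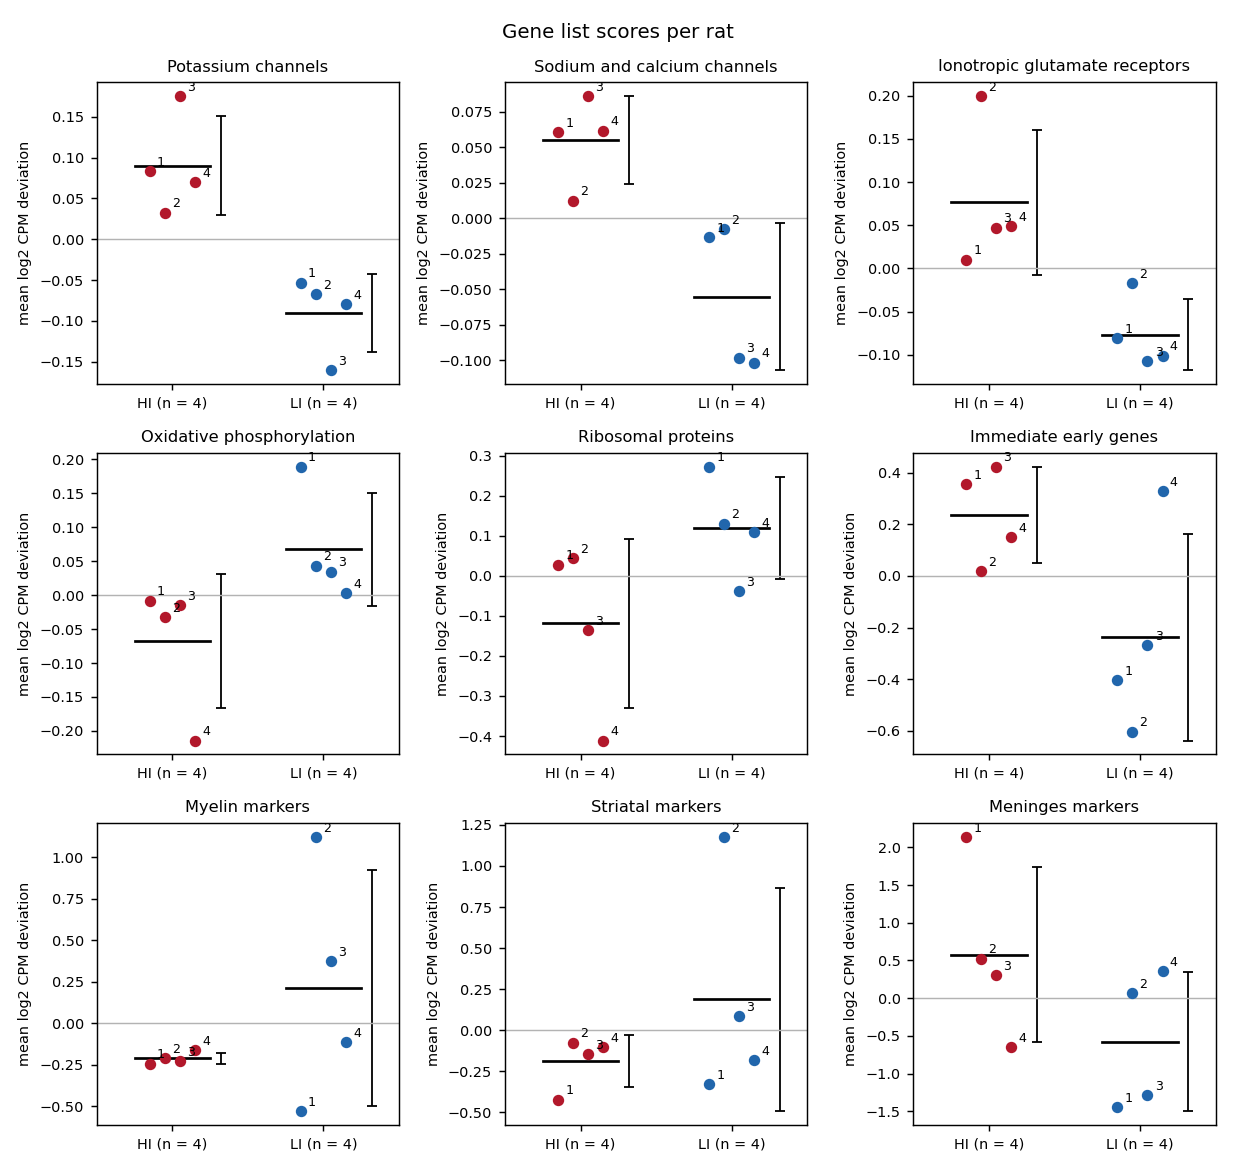
Mean log2 CPM deviation over the members of 9 gene lists in each library (points, numbered by replicate), with the group mean (line) and SD (bar) for HI and LI, n = 4 each. HI lies above LI in every library for potassium channels, sodium and calcium channels and ionotropic glutamate receptors, while the myelin and striatal scores of LI2 reach 1.12 and 1.18.

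Differences within replicates 1 and 2 and within replicates 3 and 4 were compared by list. For potassium channels the median difference was 0.09 log2 units within replicates 1 and 2 and 0.22 within replicates 3 and 4. For ionotropic receptors it was 0.07 and 0.12, for sodium and calcium channels 0.05 and 0.17, for ribosomal proteins -0.17 and -0.28, and for oxidative phosphorylation -0.13 and -0.10. Immediate early genes differed by 0.62 and 0.27 and meningeal markers by 2.37 and 0.31. Striatal markers differed by -0.73 within replicates 1 and 2, which include LI2, and by -0.04 within replicates 3 and 4. Synaptic vesicle genes differed by -0.02 and 0.19, and serotonin receptors by 0.00 and 0.21. For the channel, ionotropic receptor and oxidative phosphorylation lists the scores of HI and LI did not overlap. Their mean scores therefore had to differ in the same direction within both sets. With the ribosomal RNA share as a covariate the striatal (adjusted p = 0.141), acetylcholine receptor (0.113), serotonin receptor (0.199), oligodendrocyte precursor (0.204) and interneuron (0.332) lists no longer passed, by limma camera. Their log2 CPM medians were -0.53, 0.14, 0.00, -0.19 and -0.11 with the covariate, against -0.42, 0.15, 0.07, -0.13 and -0.12 without it.

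The other lists did not pass the threshold in limma's camera test. The adjusted p was 0.299 for chromatin enzymes, in which Hdac4 (0.50 ± 0.11, all HI above all LI) passed over the list alone, and 0.299 for glucocorticoid-responsive genes (Zbtb16, 0.44 ± 0.17). It was 0.402 for inflammation genes (Il18, 0.51 ± 0.29), 0.549 for clock genes (Dbp, -0.35 ± 0.11) and 0.549 for blood cell markers (Alas2, 0.68 ± 0.63, and -0.26 without HI1). It was 0.674 for astrocyte markers (Slc1a2, 0.54 ± 0.17), 0.679 for glycolysis (Slc16a7, 0.44 ± 0.19) and 0.679 for neuropeptides (Cartpt, -2.97 ± 1.07). It was 0.883 for heat shock genes (Atf6, 0.30 ± 0.17, and 0.13 without HI4), 0.883 for opioid and cannabinoid genes (Penk) and 0.905 for choroid plexus and ependyma markers (Foxj1, -0.83 ± 0.40, and -0.41 without LI2). The astrocyte list had a median of -0.04, a mean of 0.06 and a test direction lower in HI, and the neuropeptide list had a median of 0.03, a mean of -0.09 and a test direction higher in HI; the opioid list likewise had a median of 0.01 and a mean of -0.02 with the test higher. The ionotropic subunit gene Gria1, always reported here, differed by 0.27 ± 0.14.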

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

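The tests on LI2 and the count of gene calls over other splits were chosen after the result was seen, and the length correction and the fits without pairs of libraries were added after seeing the data; the other tests were set before their results. Of 250 sets of 4 values checked, 14 had 1 library far from the other 3 of its group, where chance gives 12.5, about 1 in 20.

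HI4 had a length slope of 0.13 log2 units per doubling, against -0.01 to 0.01 in the other HI libraries, and an oxidative phosphorylation score of -0.21, against -0.03 to -0.01. In log2 CPM, HI4 also stood apart for Tmem100 at 3.88 and Abcc9 at 4.57. HI2 stood apart for Slc16a7 at 3.32 and Il18 at 1.15, and HI3 for Scn8a at 8.50. Among LI libraries, LI2 stood apart for Adora2a at 5.29 (2.07 to 2.48 in the others), Gpr6 at 3.77 (0.76 to 1.27) and Adrbk2 at 5.29. LI4 stood apart for Fos at 5.52 (4.40 to 4.51), Reln at 7.60 and Abcc9 at 4.11, and LI1 for Tmem100 at 3.76.

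Channel and ionotropic glutamate receptor lists were higher in HI, and ribosomal protein and oxidative phosphorylation lists lower, along a trend over transcript length. The pooled 73 channel and receptor genes differed by a median of 0.13, and by 0.0739 after each library's length trend was removed, against -0.0337 to 0.0320 in random sets matched on length and expression, which argues against the length trend as the whole cause, as a median of 0.103 without HI4 and LI3 argues against those libraries. These lists were pooled because they were higher in HI in these same data, whereas the random sets were not selected, which weakens the comparison with them. For sodium and calcium channels alone the median was near 0 after the correction (-0.000424). The pooled 73 ribosomal and respiratory chain genes moved from -0.197 to -0.0733 (matched sets -0.0602 to -0.0103), and here the length trend and a group difference cannot be told apart, because the remainder lies outside the matched range but is far smaller than before. A difference between the phenotypes, a change in cell composition (pyramidal markers were higher in 15 of 21 and myelin markers lower in 22 of 22), GC content and RNA quality were not tested and stay open.

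Myelin and striatal markers were lower in HI, with LI2 far above the other libraries in Adora2a and Gpr6, and the pooled markers differed by a median of -0.43, and by -0.10 without LI2, so the difference rests largely on LI2. Of 10 striatum-enriched genes outside the fixed lists, picked after LI2 had been seen to stand apart, 8 were tested and so are also expressed in the other libraries; 7 of the 8 were higher in LI2 than the mean of the other 3 LI libraries (Adcy5 at 8.25 log2 CPM and Gng7 at 7.93 among them, but not Actn2 at 5.40), by a median of 0.921, where no other library exceeded its own group by more than 0.218. Striatal tissue in the LI2 dissection is therefore a candidate explanation for the striatal part, as a hypothesis. White matter tissue in LI2 and a difference in myelin between the phenotypes stay open. LI3 and LI4, with myelin scores of 0.37 and -0.11, lay above every HI library, and LI1, at -0.53, below every HI library. Fewer cortical pyramidal cells in LI2 alone also stay open, since its pyramidal score differed from the mean of the other LI libraries by -0.0120, within their SD of 0.224.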

How the results depend on the processing

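The fits with the ribosomal RNA covariate, the replicate term, the length correction, no ribosomal RNA genes and pairs of libraries left out were added after seeing the data. For genes past an adjusted p of 0.1, where the quasi-likelihood test gave 0, DESeq2 gave 30, edgeR's exact test 1, Fisher's exact test on summed counts 6596, an unadjusted p under 0.05 484 and the ribosomal RNA covariate 440. Fisher's test ignores the spread between libraries. It also used summed totals without TMM scaling, ribosomal RNA included. Its median log2 fold change was -0.110, against -0.007 in the quasi-likelihood test. The unadjusted count carries no adjustment over genes and lay below the 582 expected by chance. On simulated data DESeq2 made 48 false calls among 161 and edgeR's exact test 36 among 144, against 11 among 89 for the quasi-likelihood test. The simulated genes varied independently, so these shares need not hold in the real libraries. DESeq2 also adjusted p over 7440 genes only. Beyond that, the cause was not tested for DESeq2, edgeR's exact test or the covariate. All other settings, each library left out included (0 to 0), gave 0. For lists, where camera gave 22, an estimated correlation gave 0, fry 3 and the exact permutation test 0. In the last, 4 lists reached the smallest possible p of 0.0286 where 11 would be needed, so its count says nothing about stability. The estimated correlation was far above the preset 0.01 in some called lists, at 0.772 for myelin, 0.672 for meningeal markers and 0.247 for ribosomal proteins. Of the 22, only 3 lay below the preset: ionotropic (-0.0103) and metabotropic receptors (-0.0111) and sodium and calcium channels (-0.0120). In those 3 lists a larger correlation does not account for the loss. For fry the cause was not tested. Other list settings gave 15 to 22, and leaving out a library 16 to 21. No call reversed: the 22 lists kept their camera direction in every setting except 1 list without HI1 and LI2, while the median turned for serotonin receptors under both other filters and without HI2 or LI3, and for sodium and calcium channels with the length correction; 8 lists stayed past the threshold in every camera setting with the preset correlation. Of 91 named genes tested, 87 kept their sign in every setting checked for single genes, the exceptions being Drd1, Drd2, Htr2c and Alas2. Those settings were RLE factors, DESeq2, limma-voom, the filter of 1 CPM, log2(TPM + 0.1), the replicate block and each library left out. The ribosomal RNA covariate, the replicate term and the pairs of libraries left out were also among them. Signs were not compared in the other settings. With the replicate block (the replicate number as a factor) 0 genes and 20 lists passed; same-numbered libraries correlated at 0.215, 0.536, -0.05 and 0.06, and of the HI libraries only HI2 correlated best with its own number, so the numbers do not pair the libraries. At 7354416 to 9476656 counts per library, the low-count filter left 11631 genes to test and removed Nmur2.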

Other observations

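The ribosomal RNA covariate, the term for replicate numbers and the test of gene counts over splits were chosen after seeing the data; the tests over splits of the lists and of the covariate calls and the reassigned covariates were set before their results. With the log2 ribosomal RNA share as a covariate, edgeR called 440 genes, all with the same sign as without the covariate, among them all 30 DESeq2 calls. The calls lower in HI took in 11 of 38 ribosomal protein genes (Rplp0 and Rps3 among them) and 4 of 35 oxidative phosphorylation genes (Ndufa8, Ndufv1, Cox4i1 and Cox7c). The calls higher in HI took in 6 of 28 sodium and calcium channel genes (Cacna1e, Scn8a, Cacna2d1, Scn2a1 and Cacnb4 among them), 5 of 27 G protein regulators and 4 of 27 potassium channels (Kcnma1, Kcnq3, Kcnq5 and Kcnh7). The GABA-A subunit genes Gabrb1 and Gabrb2 and the serotonin receptor genes Htr1b and Htr2a were also called higher in HI. The members beyond the fixed rule were chosen after their values were seen. By Fisher's exact test against all tested genes, adjusted over 70 tests, the smallest adjusted p for over-representation of called genes were 4.88e-12 for ribosomal proteins, 0.00338 for sodium and calcium channels, 0.00965 for oxidative phosphorylation and 0.0135 for G protein regulators. Fisher's test treats genes that vary together as independent, and in camera without the covariate and with an estimated correlation none of these 4 lists passed (adjusted p = 0.225, adjusted p = 0.138, adjusted p = 0.225 and adjusted p = 0.310, limma).

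The 440 calls were more than any from the other 34 splits with the same covariate, the highest being 1, so 1 of 35 splits gave as many. That is the smallest share possible, and the covariate was chosen after seeing the data. The share therefore argues against chance for that count but cannot exclude it. Of 50 random reassignments of the covariate values to the libraries, 1 gave as many calls (2191) and the median was 0. This argues against a covariate in random order as the cause. Other covariates that set HI4 and LI3 apart from the other libraries were not tested. The count was 0 without HI4 and 0 without LI3, 2 without LI4, 7 without LI1, 20 without HI2, 37 without HI3, 359 without LI2 and 994 without HI1, so it rests on HI4 and LI3, the libraries with the least ribosomal RNA, and falls to few calls without LI4 or LI1 as well.

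Without the covariate, only 1 of the 35 splits of the 8 libraries, the real one, called as many lists (22, against 17 in the highest other). That is the smallest share that 35 splits allow, so it argues against chance for the number of lists but cannot exclude it. Every other split also called lists, from 1 to 17, and the split with HI1, HI2, LI1 and LI3 on the same side called 15. That split holds as many HI as LI libraries on each side. Passing camera with the preset correlation therefore does not by itself point to impulsivity. In camera with an estimated correlation 0 of the 22 lists passed. For genes the real count was 0, so all 35 of 35 splits necessarily gave as many and the comparison says nothing about chance. The split of replicates 1 and 2 against replicates 3 and 4, the highest of the other splits, called 2923 genes. Each side holds as many HI as LI libraries, so this count is not about impulsivity. It points to a structure of the libraries that goes with both the replicate number and the ribosomal RNA share, which cannot be told apart here. A term for that split left 0 gene calls and 21 list calls, and within replicates 1 and 2, and within 3 and 4, edgeR called 0 genes. The HI minus LI differences within these 2 sets of libraries were correlated across genes (Spearman correlation = 0.306, genes not being independent replicates).

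Cartpt, a neuropeptide gene, showed a pattern in single libraries, at 4.82, 3.74 and 2.31 log2 CPM in LI2, LI3 and LI4 but -0.86 in LI1, against 1.95, 0.48, -0.19 and -1.43 in HI1 to HI4. Nmur2 had 29 and 59 counts in LI2 and LI3 and 20 in HI1, but 0 in LI1 and HI4.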
